A study of Homo sapiens with 50 samples.

How the data were processed

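Poly-A RNA was sequenced from sorted live cells of healthy B-cell development, from leukaemia cells of patients with B-cell precursor acute lymphoblastic leukaemia (B-ALL), and from 2 human leukaemia cell lines, REH and SEM, that carried guide RNAs against ERG or control guides. The values deposited by the authors are transcript abundances in TPM (transcripts scaled to the same total in each library), with 59611 gene names in each table and 1 column per library. Column totals ran from 999999.9 to 1000000.12 TPM, and the tables held 0 mitochondrially encoded genes. Per the submitters' processing notes, reads were aligned with STAR 2.7.3a, the genome builds named were GRCh37 and hg19, and DESeq2 was named without a version or a role. The counter, the annotation, the strand setting and any filter are not given in the sources used here. TPM keeps no depth, so the read depth of each library is unknown, and no interval or detection limit that needs it was computed. A gene with a value of 0 is described as listed at 0.

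Gene types and chromosomes were taken by name from GENCODE release 29, which is annotated on another build, so no coordinate was used or printed. Of the 59611 names, 53519 (89.8%) were found in it. Y-linked genes, XIST, TSIX, JPX and FTX (501 genes) were left out of every test, which left 59110 genes. Reads of genes with near-identical copies, such as the HLA class II genes, IGLL1 and IGLL5, could have been split between the copies by the authors' counting, so their levels are uncertain.

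Groups were taken from the titles and cell types in the labels. In the labels, 1 CLP library and the iAMP21 libraries carry a further tag that names another source than their titles. The titles were followed: the mean TPM of DPPA4 was 38.8 ± 15.7 (SD, n = 4) in CLP against at most 0.176 in the 5 leukaemia subtypes with at least 3 libraries, and that of DSC3 was 0.051 ± 0.0721 (SD, n = 2) in iAMP21 against 62.7 ± 21.7 (SD, n = 2) in REH with control guides. The labels do not say whether every library of patients came from a different person, or whether the libraries of a cell line were separate cultures. Each cell line library had its own guide, so a p there measures the spread between these samples. Pearson correlations of log2(TPM + 1) between libraries of a group were 0.784 to 0.918 in CLP, 0.788 to 0.898 in ETV6-RUNX1 and 0.960 to 0.967 in REH with ERG guides, and no library was identical to another.

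Values were analysed as log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 differences are therefore on the log2(TPM + 1) scale, which understates the change of low genes. Genes entered a test with at least 1 TPM in at least 3 libraries of the fit, or in at least 2 for the cell lines. The 12 comparisons, their tests, the 22 gene lists, the naming rule and the alternatives were fixed before the data were examined, except where an alternative is said to have been chosen later. The healthy steps were fitted on the 15 healthy libraries, the leukaemia comparison on the 40 primary libraries, the subtype comparisons on the 25 patient libraries, each knockout effect on the 5 libraries of its line and their difference on all 10. Contrasts over several groups weighted the groups equally. The single hyperdiploid library entered no contrast.

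Named genes followed 1 rule: ERG in every comparison, the 6 genes with the largest rise and the 6 with the largest fall among called genes with a mean of at least 5 TPM on the higher side, and up to 4 called members of each list. No overlap between the libraries of the compared sides was required for the largest changes, except against a mean of other subtypes. This requirement was also waived for the difference between the lines, which has no pair of sides. Where it applied, lack of overlap in a gene named for its large change followed from the choice and adds no support. Immunoglobulin and T-cell receptor segments, HLA genes, ribosomal protein, histone and small RNA genes, pseudogenes and clone-named loci were left out of the largest changes. An early version of this rule kept protein-coding genes only and was replaced by the written one.

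The lists covered stem and early progenitor genes, V(D)J recombination and pre-B receptor genes, B-lineage transcription factors, B-cell receptor and mature B-cell genes, MHC class II genes, proliferation genes, MYC and ribosome biogenesis genes, p53 target genes, apoptosis regulators of the BCL2 family, interferon response genes, immediate early and heat shock genes, genes associated with KMT2A rearrangement, with ETV6-RUNX1 and with BCR-ABL1 or BCR-ABL1-like leukaemia, chromosome 21 genes of the commonly amplified region, leukaemia and lymphoid driver genes, and markers of myeloid, T and NK, erythroid, megakaryocyte, plasma and plasmacytoid dendritic cells. They were written from general knowledge. Lists were tested 2-sided with camera in limma at a preset correlation of 0.01, adjusted within a comparison, and again with a correlation estimated from the data. Mean log2 levels of the other-cell-type lists were compared by 2-sided permutation tests, exact where the regroupings could be enumerated and otherwise with 100000 resamples, in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Figures were drawn with matplotlib 3.10.9.

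In each healthy step, libraries with the same replicate number deviated together from their group means: the correlation of deviations was over 0.1 in 21 of 21 same-number pairs (0.155 to 0.544), against 8 of 63 pairs with different numbers. The pairing comes from these data, since the labels do not say what the numbers stand for. Results with the number as a block are given beside the healthy results where they move a count. The block was a fixed effect of the number, and of the guide for the difference between the lines. In the leukaemia comparison it was a random effect instead (duplicateCorrelation in limma). There only healthy libraries with the same number shared a block, and each patient library had its own.

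Each model was tested on simulated data with 100 genes changed by a log2 fold of 1 and 100 by a log2 fold of 3. The changed genes were drawn only among those of higher mean level, with independent normal noise of the same spread in all groups. Pairing of libraries and correlation between genes were not simulated, so the recoveries may be too high for the real data. At a log2 fold of 3 it recovered 65% of the changed genes for Pro-B against CLP, 93% for B-ALL against Pro-B and Pre-B, 91% for ETV6-RUNX1, 53% for BCR-ABL1 against BCR-ABL1-like, 86% for REH and 91% for SEM. At a log2 fold of 1 it recovered 0%, 20%, 18%, 1%, 17% and 16% in the same order. The alternatives tried were a pseudocount of 0.1 TPM, no filter, quantile normalization, array quality weights, fits on fewer groups, other reference groups, the replicate block and leaving out each library in turn. The chromosome 21 median was at first computed on centred protein-coding genes, which departed from the plan. The planned version is the reported one, and the other is kept as an alternative.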

Results

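RNA levels were measured in 50 libraries, of which 15 came from healthy B-cell development, 25 from patients with B-ALL and 10 from cell lines. The healthy cells were common lymphoid progenitors (CLP, n = 4), Pro-B cells (n = 4), Pre-B cells (n = 4) and Immature-B cells (n = 3). The leukaemia groups were ETV6-RUNX1 (n = 7), KMT2A-rearranged (KMT2Ar, n = 5), BCR-ABL1 (n = 3), BCR-ABL1-like (n = 3), Other B-ALL (n = 4), intrachromosomal amplification of chromosome 21 (iAMP21, n = 2) and hyperdiploid (n = 1). REH is an ETV6-RUNX1 leukaemia line and SEM a KMT2A-rearranged one, and each had 3 libraries with ERG guides and 2 with control guides. Libraries listed between 17119 and 28498 genes above 0, and their read depth is unknown because only TPM was deposited.

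The transcription factor ERG, which the cell line part of the series targets, was high in early healthy stages and fell at the Pre-B stage. Its mean TPM was 37.6 ± 21.2 (SD, n = 4) in CLP, 53.6 ± 35.2 (SD, n = 4) in Pro-B, 4.70 ± 4.10 (SD, n = 4) in Pre-B and 0.187 ± 0.0917 (SD, n = 3) in Immature-B cells. The step from Pro-B to Pre-B changed ERG by a log2 of -3.27 ± 0.68 (SE; limma adjusted p = 0.0176), with every Pre-B library below every Pro-B library. That call was lost without a filter (adjusted p = 0.0548) and without Pre-B replicate 1, Pre-B replicate 2, Pro-B replicate 3 or Pro-B replicate 4 (adjusted p = 0.0586, 0.0592, 0.0765 and 0.0577), with a range of 0.000129 to 0.0765 over 16 alternatives. In leukaemia, ERG was highest in iAMP21, at 337.7 ± 202 TPM (SD, n = 2), and in ETV6-RUNX1, at 195.2 ± 116 TPM (SD, n = 7), and lowest in KMT2Ar, at 35.5 ± 14.3 TPM (SD, n = 5). BCR-ABL1, BCR-ABL1-like and Other B-ALL had means of 101.8, 111.8 and 71.1 TPM. Against the other subtypes ERG was not called: the log2 difference was 1.55 ± 0.48 (SE; limma adjusted p = 0.065) for ETV6-RUNX1, -1.40 ± 0.54 (SE; adjusted p = 0.128) for KMT2Ar and 2.11 ± 0.78 (SE; adjusted p = 0.416) for iAMP21. For ETV6-RUNX1 the adjusted p ran from 0.0275 to 0.164 over 29 alternatives. ERG was called there without ETV6-RUNX1 replicate 6 (limma adjusted p = 0.045), without BCR-ABL1 replicate 2 (adjusted p = 0.0275) or without BCR-ABL1-like replicate 2 (adjusted p = 0.0411). It was also called with the replicate number as a block, although same-number subtype libraries did not deviate together (median correlation 0.007 over 34 pairs). For KMT2Ar the adjusted p ran from 0.0386 to 0.339 over 29 alternatives, and ERG was called lower without BCR-ABL1 replicate 3 (adjusted p = 0.0386) and with array quality weights (adjusted p = 0.0405).

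**Figure D1:**
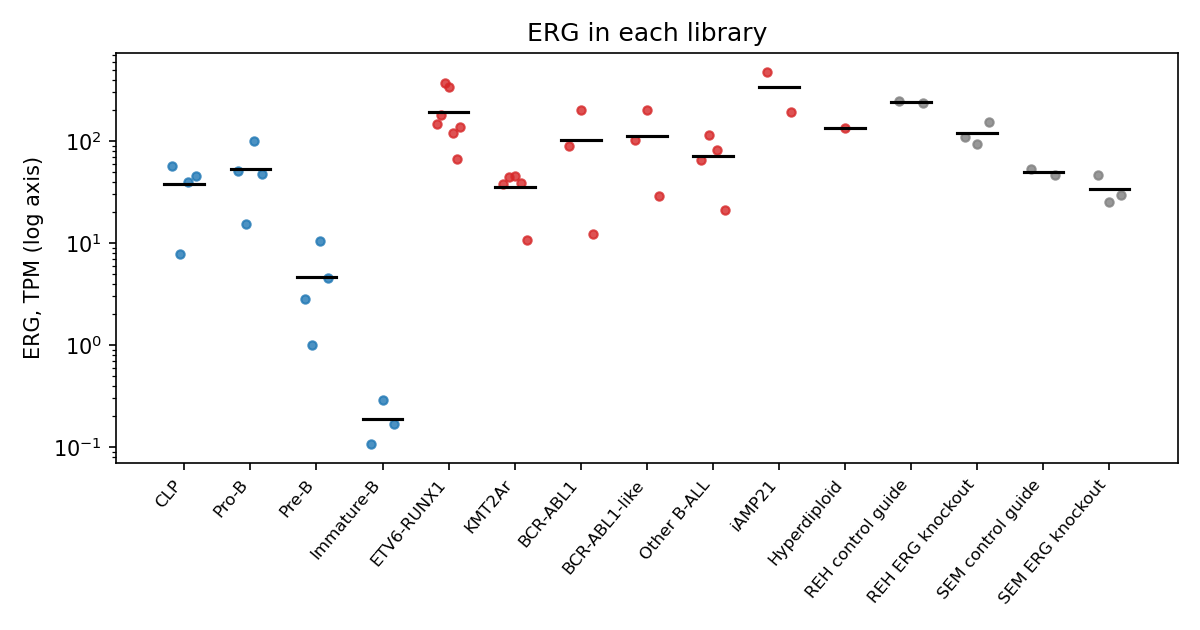
ERG level in TPM on a log axis for each library of the 15 groups, with a line at each group mean. ERG lies at or below 10.45 TPM in every Pre-B and Immature-B library, and between 66.3 and 375.7 TPM in the ETV6-RUNX1 libraries.

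The step from CLP to Pro-B asks which genes mark the entry into the B lineage. LILRA4, a plasmacytoid dendritic cell gene, fell from 53.7 ± 33.3 to 0.492 ± 0.984 TPM (SD, n = 4 each; log2 difference -5.16 ± 0.62 (SE), limma adjusted p = 0.000473). The progenitor gene SPINK2 fell from 2200 ± 1300 to 98.6 ± 24.9 TPM, IRF8 from 170.7 to 38.9 TPM, and HOXA7 from 15.6 to 1.08 TPM, while CD79B, a signalling chain of the B-cell receptor, rose from 341.5 to 1023 TPM. For each of these genes the 4 Pro-B libraries lay on 1 side of the 4 CLP libraries, as the naming rule required of the largest changes. Of 20948 genes tested, 33 were higher and 173 lower in Pro-B. With the replicate number as a block, 221 were higher and 635 lower, and these included all 206 genes called without it in the same direction. The calls for LILRA4, NPTX2, PRSS1 and SPON1 held under every alternative tried. Those for IRF8 and HOXA7 were lost in the fit on the Pro-B and CLP libraries alone, that for HOXA7 also with a pseudocount of 0.1 TPM, with adjusted p from 0.000835 to 0.0834 over 16 alternatives for IRF8 and from 0.000578 to 0.0834 over 15 for HOXA7. Those for SPINK2 (adjusted p = 0.0227) and CD79B (adjusted p = 0.0253) were lost without CLP replicate 1, CLP replicate 3, Pro-B replicate 1, Pro-B replicate 3 or Pro-B replicate 4. Both were also lost with no filter, SPINK2 with a pseudocount of 0.1 TPM and CD79B in the fit on the 2 groups alone. Over 16 alternatives the adjusted p ran from 0.00311 to 0.0873 for SPINK2 and from 0.00361 to 0.203 for CD79B. The count fell to 96 without CLP replicate 3, 75 without Pro-B replicate 1, 121 without Pro-B replicate 3 and 77 without Pro-B replicate 4.

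Among the lists, 2 of 13 stem and early progenitor genes fell from CLP to Pro-B, 8 when adjusted over the list alone, and none rose (camera adjusted p = 9.96e-15, or adjusted p = 0.00748 with an estimated correlation). Of 16 KMT2A-rearrangement associated genes, HOXA5, HOXA6, HOXA7, RUNX2 and 1 other fell, 9 when adjusted over the list alone (camera adjusted p = 9.96e-15, or 0.035 with an estimated correlation). Of 22 B-cell receptor and mature B-cell genes 3 rose, among them BLK and CD79B (camera adjusted p = 4.01e-06, or 0.0641 with an estimated correlation). BACH2 rose and IRF8 fell among the 21 B-lineage transcription factors (camera adjusted p = 0.00903, or 0.379 with an estimated correlation). Markers of other cells also moved: the mean log2 level of myeloid markers was 6.97 ± 0.93 (SD, n = 4) in CLP and 4.14 ± 1.14 (SD, n = 4) in Pro-B, and that of plasmacytoid dendritic markers was 4.49 ± 0.25 and 2.29 ± 0.29. Each had an exact permutation p of 0.0286, the smallest that 4 against 4 libraries allow, and an adjusted p of 0.189 over 66 such tests. These regroupings took the libraries as independent and did not keep the same-number pairs together. All 14 myeloid markers fell when adjusted over the list alone, and 0 did over all genes in limma. CD3E and TRBC2 of the T and NK markers fell as well.

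The step from Pro-B to Pre-B asks which genes go with pre-B receptor signalling and the loss of progenitor genes. CD34, a progenitor surface protein, fell from 68.8 ± 16.6 to 1.02 ± 0.537 TPM (SD, n = 4 each; log2 difference -5.12 ± 0.41 (SE), limma adjusted p = 1.08e-05). DNTT, which adds bases at V(D)J joints, fell from 10710 ± 4800 to 548.1 ± 479 TPM (log2 difference -4.53 ± 0.76 (SE), adjusted p = 0.00323). SPIB rose from 7.78 ± 9.53 to 155.8 ± 76.8 TPM and IRF4 from 58.8 to 609.9 TPM, both transcription factors of B cells. IGLL5 rose from 60.9 ± 69.9 to 1957 ± 684 TPM, and the progenitor genes BAALC and SOCS2 fell, SOCS2 by 4.36 on the log2 scale. In all of these genes the 4 Pre-B libraries lay on 1 side of the 4 Pro-B libraries, as the naming rule required of the largest changes. The calls for all of these genes held under every alternative tried. In total 244 genes were higher and 78 lower in Pre-B, and 592 and 330 with the replicate number as a block, which kept all 322 in the same direction. Without Pro-B replicate 4 the count was 203.

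Of 13 stem and early progenitor genes 3 fell in Pre-B (CD34, BAALC and LMO2), 6 when adjusted over the list alone (camera adjusted p = 8.81e-16, or 0.0157 with an estimated correlation). Of 22 B-cell receptor and mature B-cell genes 4 rose and 1 fell, 10 and 1 when adjusted over the list alone (camera adjusted p = 9.49e-09, or 0.0198 with an estimated correlation). SOCS2 and SLC2A5 were among the 3 that fell of 15 BCR-ABL1 and BCR-ABL1-like associated genes (camera adjusted p = 2.98e-06, or 0.0497 with an estimated correlation). PLD4 and SERPINF1 rose among 6 plasmacytoid dendritic markers (camera adjusted p = 1.06e-05, or 0.0157 with an estimated correlation), whose mean log2 level went from 2.29 ± 0.29 to 3.48 ± 0.45 (SD, n = 4 each; exact permutation p = 0.0286, adjusted p = 0.189). The mean level of plasma cell markers went from 4.84 ± 0.32 to 5.56 ± 0.06 with the same exact permutation p and adjusted p. BIK rose among 14 apoptosis regulators of the BCL2 family (camera adjusted p = 0.0351, or 0.3 with an estimated correlation).

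The step from Pre-B to Immature-B was the largest of the healthy ones by called genes and asks what goes with the exit from the cell cycle and the mature receptor. The proliferation genes BIRC5, at 370.4 TPM in Pre-B and 17.9 TPM in Immature-B, TYMS, from 267.2 ± 96.9 to 12.4 ± 8.42 TPM (SD, n = 4 and 3), and MKI67, from 126.9 to 7.45 TPM, all fell (BIRC5 log2 difference -4.37 ± 0.37 (SE), limma adjusted p = 3.88e-05). The surrogate light chain genes IGLL1, from 7895 ± 4350 to 364.3 ± 197 TPM, and VPREB1, from 5070 to 476.8 TPM, fell with them. FCRL1 rose from 44.3 to 483.4 TPM, the complement receptor CR2 from 2.31 to 57.4 TPM, and HLA-DOB from 9.19 to 181.7 TPM (log2 difference 4.16 ± 0.55 (SE), adjusted p = 0.000473). Every Immature-B library lay beyond every Pre-B library in these genes, as the naming rule required of the largest changes. The calls for these genes held under every alternative tried, except that for CR2 with a pseudocount of 0.1 TPM (adjusted p from 0.000949 to 0.0942 over 15 alternatives). Of the genes tested 324 were higher and 390 lower in Immature-B, 142 and 398 with a pseudocount of 0.1 TPM, and 1095 and 1981 with the replicate number as a block, which kept all 714 in the same direction. The count was 328 without Immature-B replicate 3, 340 without Immature-B replicate 4 and 445 without Pre-B replicate 3. ERG fell by 1.99 on the log2 scale without being called (adjusted p = 0.189), and by 2.49 with the block (adjusted p = 0.00057); over 15 alternatives the adjusted p ran from 0.00057 to 0.423.

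Of 26 proliferation genes 18 fell and 0 rose, 25 and 0 when adjusted over the list alone (camera adjusted p = 2.05e-50, or 0.0246 with an estimated correlation). Of 12 MHC class II genes 5 rose, among them HLA-DOB and HLA-DQA1, 10 when adjusted over the list alone (camera adjusted p = 5.08e-13, or 0.0246 with an estimated correlation). Of 22 B-cell receptor and mature B-cell genes 7 rose, among them CR2, LTB, FCRL1 and CD40 (camera adjusted p = 1.59e-15, or 0.00684 with an estimated correlation). Of 11 V(D)J recombination and pre-B receptor genes 5 fell (IGLL1, ADA, VPREB1, DNTT and 1 other), 7 when adjusted over the list alone (camera adjusted p = 1.72e-10, or 0.154 with an estimated correlation). CLEC4C rose among 6 plasmacytoid dendritic markers, 3 when adjusted over the list alone (camera adjusted p = 0.00119, or 0.0264 with an estimated correlation), and their mean log2 level went from 3.48 ± 0.45 (SD, n = 4) to 4.85 ± 0.11 (SD, n = 3; exact permutation p = 0.0571, adjusted p = 0.269). The CLEC4C call was lost with a pseudocount of 0.1 TPM and without Immature-B replicate 1, with adjusted p from 0.00243 to 0.073 over 14 alternatives. Of the interferon response genes, MX1 rose (camera adjusted p = 0.0031 for 18 genes, or 0.154 with an estimated correlation). The calls for MX1, HLA-DQA1, CD40 and DNTT did not hold under every alternative tried.

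Leukaemia was compared with the Pro-B and Pre-B stages to ask how the leukaemic cells differ from the healthy stages nearest to them. LPAR6, a lysophospholipid receptor gene, was higher in leukaemia, with means of 106.1 to 237.6 TPM in the 5 subtypes against 8.13 in Pro-B and 4.55 in Pre-B (log2 difference 4.30 ± 0.38 (SE), limma adjusted p = 5.12e-10). DPPA4 was lower, at 0.176 TPM or less in each subtype mean against 29.6 ± 7.61 TPM in Pro-B and 14.5 ± 3.92 TPM in Pre-B (SD, n = 4 each; log2 difference -4.35 ± 0.23 (SE), adjusted p = 4.68e-16). The 22 leukaemia libraries all lay above the 8 healthy libraries for LPAR6 and HSPB1, and all below them for DPPA4 and SCRN1. Such lack of overlap was required of the largest changes by the naming rule. The proliferation gene TOP2A was lower in leukaemia (log2 difference -3.52 ± 0.71 (SE), adjusted p = 0.000863), from 1027 TPM in Pro-B and 960.3 TPM in Pre-B. IRF4 and IGLL1 were lower too, by log2 differences of -3.91 ± 0.45 and -3.41 ± 0.73 (SE), and the calls for all of these genes held under every alternative tried. ERG was higher than the mean of Pro-B and Pre-B (log2 difference 2.29 ± 0.44 (SE), adjusted p = 0.000434), which rested on Pre-B: against Pro-B alone the adjusted p was 0.616, within a range of 1.88e-07 to 0.616 over 41 alternatives. FLT3 and SOCS2 were likewise higher and lost against Pro-B alone, with adjusted p of 0.0943 and 0.562, the highest of their 41 alternatives (from 3.5e-06 and 2.06e-11). Of 26562 genes tested 978 were higher and 1456 lower, of which 832 and 1207 differed by a log2 of more than 1. With the replicate number as a random block shared only by healthy libraries, 436 were higher and 831 lower, all of them among the genes called without it.

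Of 26 proliferation genes 25 were lower in leukaemia, all 26 when adjusted over the list alone (camera adjusted p = 1.1e-32, or 0.0291 with an estimated correlation). Of 18 BCR-ABL1 and BCR-ABL1-like associated genes 10 were higher, among them ADGRE5 and SOCS2 (camera adjusted p = 7.64e-09, or 0.0291 with an estimated correlation). Their mean log2 level was 5.36 in BCR-ABL1, 5.28 in BCR-ABL1-like, 4.37 in ETV6-RUNX1, 3.61 in Other B-ALL and 3.02 in KMT2Ar, against 3.56 in Pro-B and 2.85 in Pre-B. Of 12 ETV6-RUNX1 associated genes 5 were higher, among them KCNN1 and DSC3 (camera adjusted p = 0.000344, or 0.0575 with an estimated correlation). ETV6-RUNX1 alone carried that rise: the mean log2 level of the list was 5.86 there and 1.42 to 1.88 in the other 4 subtypes, against 1.85 in Pro-B and 1.88 in Pre-B. NCL, NOLC1 and ODC1 were the 3 lower genes of the 16 MYC and ribosome biogenesis genes (camera adjusted p = 0.00109, or 0.18 with an estimated correlation). TNFRSF10B, TP53I3, BBC3 and BAX were the 4 higher genes of the 18 p53 targets (camera adjusted p = 0.0174, or 0.173 with an estimated correlation), and JUN the 1 higher gene of the 14 immediate early and heat shock genes (camera adjusted p = 0.0201, or 0.536 with an estimated correlation). The calls for ODC1 and TNFRSF10B held under every alternative tried, and those for NCL, NOLC1, TP53I3, BBC3, BAX and JUN did not. Of 14 myeloid markers 8 were lower, led by S100A8 and S100A9 (camera adjusted p = 2.24e-06, or 0.173 with an estimated correlation). Their mean log2 level was 2.13 ± 1.18 (SD, n = 22) in leukaemia against 3.87 ± 1.08 (SD, n = 8), a difference of -1.75 (permutation p = 0.0025, adjusted p = 0.119). That permutation took the 8 Pro-B and Pre-B libraries as independent, although those with the same number deviate together. The lists of erythroid markers (0 of 12 called; camera adjusted p = 0.329), megakaryocyte markers (1 of 6 lower; camera adjusted p = 0.185) and plasma cell markers (2 of 7 lower; camera adjusted p = 0.246) were not called. The mean level of megakaryocyte markers was 0.33 ± 0.28 (SD, n = 22) in leukaemia against 0.71 ± 0.41 (SD, n = 8; permutation p = 0.013, adjusted p = 0.172).

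**Figure D2:**
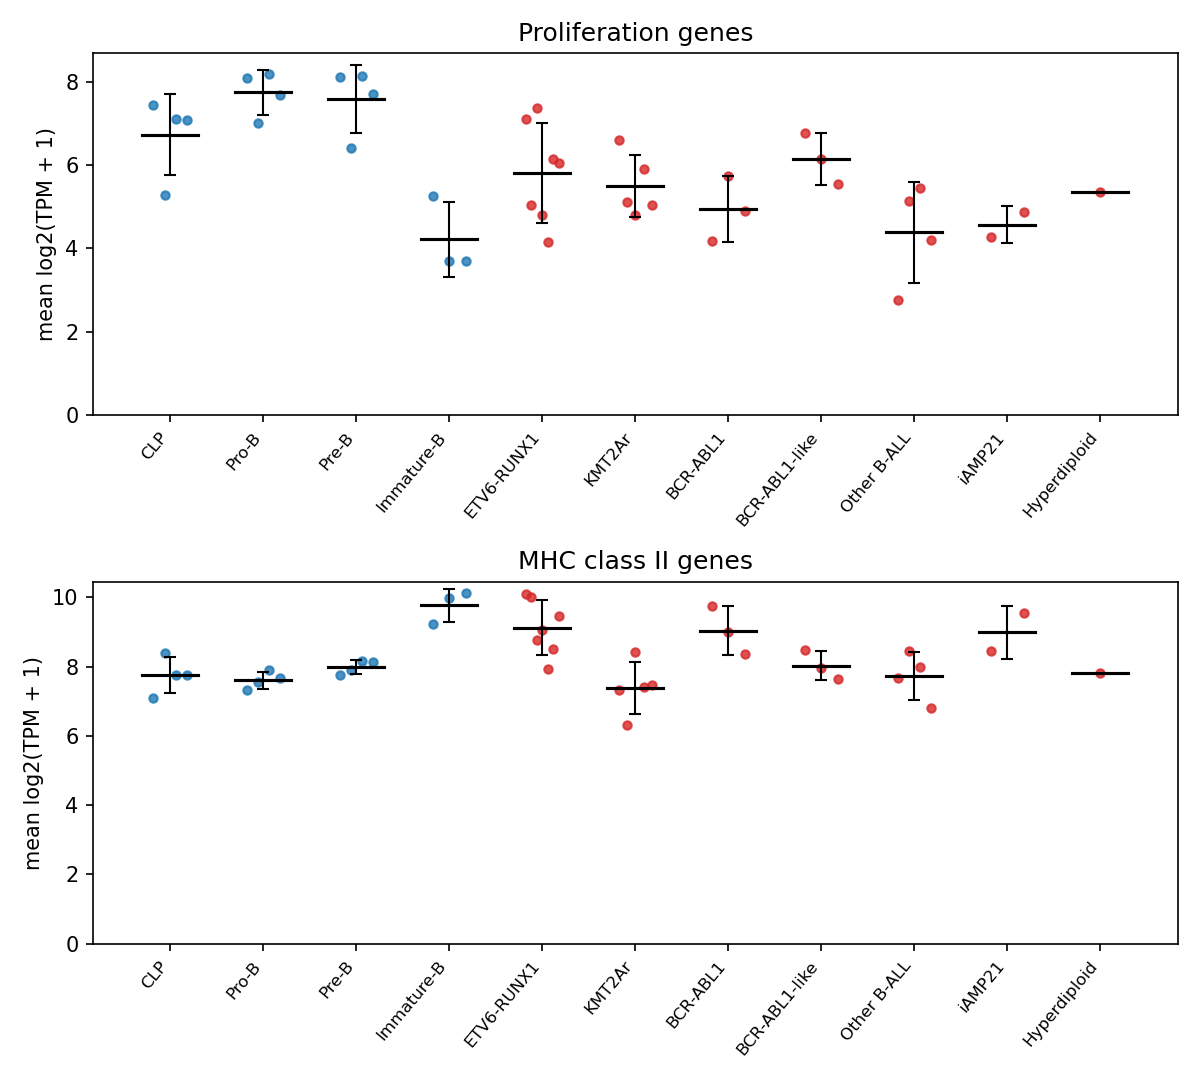
Mean log2(TPM + 1) over the proliferation genes and over the MHC class II genes for each primary library, by group, with a line at the group mean and bars of 1 SD. Proliferation genes average 7.75 in Pro-B and 4.21 in Immature-B, and the leukaemia subtypes with at least 3 libraries lie between 4.38 and 6.15.

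ETV6-RUNX1 leukaemia was compared with KMT2Ar, BCR-ABL1, BCR-ABL1-like and Other B-ALL to find the genes that set it apart. DSC3, a desmosomal cadherin gene, stood at 104.1 ± 54.3 TPM (SD, n = 7) in ETV6-RUNX1 and at 0.0292 TPM or less in the other 4 group means (log2 difference 6.51 ± 0.31 (SE), limma adjusted p = 1.99e-13). BIRC7, an inhibitor of apoptosis, reached 300.4 ± 402 TPM against at most 0.0693, and the G protein subunit gene GNG11 1159 ± 482 TPM against at most 137.4. SRGN, a proteoglycan gene of blood cells, was lower, at 18.7 ± 19.7 TPM against 320.7 to 615.5 (log2 difference -5.19 ± 0.59 (SE), adjusted p = 3.24e-06). For these genes the 7 ETV6-RUNX1 libraries did not overlap the 15 others. RAG1, which cuts DNA in V(D)J recombination, was higher by a log2 of 3.17 ± 0.59 (SE; adjusted p = 0.00152), and each of these calls held under every alternative tried. Of 24132 genes 782 were higher and 330 lower.

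The ETV6-RUNX1 associated list, fixed beforehand from general knowledge, had 9 of 12 genes higher and none lower, 11 when adjusted over the list alone (camera adjusted p = 2.68e-83, or 2.43e-06 with an estimated correlation). MHC class II genes were higher, with 3 of 12 called, HLA-DOB, HLA-DMA and HLA-DPA1, and 6 when adjusted over the list alone (camera adjusted p = 4.55e-05, or 0.386 with an estimated correlation). Of these 3 only the HLA-DOB call held under every alternative tried. The mean log2 level of the list was 9.11 ± 0.80 (SD, n = 7) in ETV6-RUNX1 and near it, at 9.03 ± 0.70 (SD, n = 3), in BCR-ABL1. It was 8.03 in BCR-ABL1-like, 7.72 in Other B-ALL and 7.39 in KMT2Ar. Of 14 myeloid markers 3 were lower (S100A9, LYZ and CSF1R; camera adjusted p = 5.96e-05, or 0.311 with an estimated correlation). Of 14 T and NK markers 3 were lower and CD247 was higher (camera adjusted p = 4.55e-05, or 0.311 with an estimated correlation). The mean log2 level of myeloid markers was 1.30 ± 0.55 (SD, n = 7) against 2.51 ± 1.21 (SD, n = 15), a difference with an exact permutation p of 0.00467 and an adjusted p of 0.119.

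**Figure D3:**
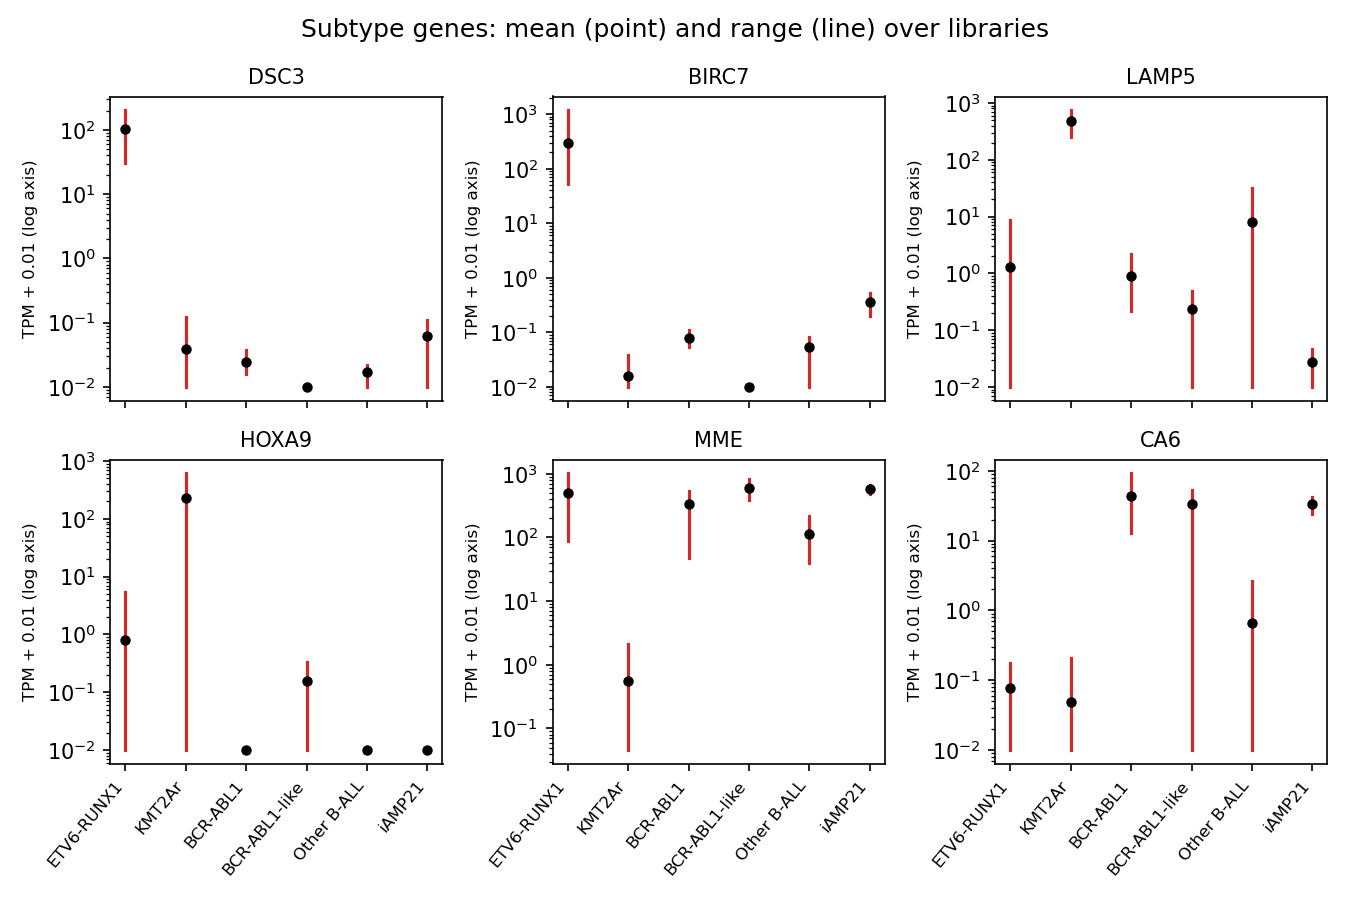
Level of DSC3, BIRC7, LAMP5, HOXA9, MME and CA6 by leukaemia subtype, as TPM + 0.01 on a log axis, with a point at the mean and a line from the lowest to the highest library. DSC3 averages 104.1 TPM in ETV6-RUNX1, and MME averages 0.537 TPM in KMT2Ar.

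KMT2Ar leukaemia was set against the same kind of mean to ask which genes go with the rearrangement. LAMP5 stood at 476.7 ± 193 TPM (SD, n = 5) and at 7.89 TPM or less in the other 4 group means (log2 difference 8.09 ± 0.64 (SE), limma adjusted p = 8.82e-09), although the healthy Pre-B cells held 141.8 ± 70.8 TPM. MEIS1, a cofactor of HOX proteins, stood at 73.1 ± 47.9 TPM against at most 0.27, and the proteoglycan gene CSPG4 at 61.1 ± 19.8 TPM. HOXA9 averaged 234.1 ± 236 TPM against at most 0.797 (log2 difference 6.12 ± 0.84 (SE), adjusted p = 5.31e-05), but was listed at 0 in KMT2Ar replicate 1. MME, which encodes the surface antigen CD10, was at 0.537 ± 0.866 TPM in KMT2Ar and between 113.3 and 596.5 TPM in the other group means (log2 difference -7.54 ± 0.52 (SE), adjusted p = 7.01e-10). The 5 KMT2Ar libraries did not overlap the 17 others for LAMP5, MEIS1, CSPG4 and MME. The receptor kinase gene FLT3 averaged 1069 ± 578 TPM, the highest mean of the primary groups. All of these calls held under every alternative tried. In total 1001 genes were higher and 508 lower, and the count was 835 without KMT2Ar replicate 2 and 731 without KMT2Ar replicate 4.

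The KMT2A-rearrangement list, also fixed beforehand, had 13 of 17 genes higher, 14 when adjusted over the list alone (camera adjusted p = 1.17e-35, or 0.0125 with an estimated correlation). Of 18 BCR-ABL1 and BCR-ABL1-like associated genes 8 were lower (camera adjusted p = 1.81e-09, or 0.0325 with an estimated correlation), and of 12 ETV6-RUNX1 associated genes 4 were lower (camera adjusted p = 5.29e-05, or 0.0325 with an estimated correlation). The latter reflects ETV6-RUNX1 on the other side, at a mean log2 level of 5.86, since KMT2Ar at 1.57 lay within the 1.42 to 1.88 of the remaining subtypes. Of 12 MHC class II genes 3 were lower, HLA-DPB1, HLA-DRA and CD74, and 6 when adjusted over the list alone (camera adjusted p = 6.72e-06, or 0.208 with an estimated correlation). HLA-DPB1 held under every alternative, while HLA-DRA was lost with no filter, under quantile normalization, with the replicate number as a block and without KMT2Ar replicate 2, 4 or 5, BCR-ABL1 replicate 3 or BCR-ABL1-like replicate 2 (adjusted p from 0.0518 to 0.166), within a range of 0.0117 to 0.304 over 29 alternatives. The myeloid genes CSF1R, LYZ and VCAN were higher (camera adjusted p = 0.0853 for the 14 myeloid markers), at means of 60.3 ± 34.3 TPM for CSF1R and 229.5 ± 282 TPM for LYZ (SD, n = 5). The mean log2 level of myeloid markers was 5.10 in KMT2Ar replicate 3 and 1.77 to 2.36 in the other 4 KMT2Ar libraries, and the calls for CSF1R, LYZ and VCAN held without that library. The mean log2 level of plasma cell markers was 3.86 ± 0.70 (SD, n = 5) in KMT2Ar against 4.91 ± 0.67 (SD, n = 17; exact permutation p = 0.00904, adjusted p = 0.149), while that of myeloid markers gave an exact permutation p = 0.222 (adjusted p = 0.581).

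BCR-ABL1 and BCR-ABL1-like leukaemia together were set against ETV6-RUNX1, KMT2Ar and Other B-ALL. CA6, a secreted carbonic anhydrase gene, averaged 43.1 ± 42.8 TPM in BCR-ABL1 and 33.6 ± 29.2 TPM in BCR-ABL1-like (SD, n = 3 each) and 0.657 TPM or less in the other group means (log2 difference 4.19 ± 0.57 (SE), limma adjusted p = 0.000579). PON2 averaged 32.8 ± 10.6 and 49.6 ± 29.6 TPM against at most 7.97 (log2 difference 3.82 ± 0.52 (SE), adjusted p = 0.000579). JCHAIN, the joining chain of secreted antibodies, averaged 2276 ± 3640 and 3546 ± 3130 TPM (log2 difference 5.15 ± 0.99 (SE), adjusted p = 0.0154), and its call was lost with no filter, with BCR-ABL1 alone, without BCR-ABL1 replicate 1 (adjusted p = 0.0819) and without BCR-ABL1-like replicate 1 (adjusted p = 0.0641), within a range of 0.00876 to 0.298 over 31 alternatives. The plasma cell markers, a list that holds JCHAIN, had a mean log2 level of 5.22 ± 0.41 (SD, n = 6) against 4.46 ± 0.81 (SD, n = 16; exact permutation p = 0.038, adjusted p = 0.209), and T and NK markers 2.89 ± 0.92 against 1.90 ± 0.87 (exact permutation p = 0.0434, adjusted p = 0.22). The libraries of the compared sides overlapped in each of these genes, and the calls for CA6, PON2, DSC3 and KCNN1 held under every alternative tried. In total 46 genes were higher and 25 lower, 32 and 32 with a pseudocount of 0.1 TPM, 16 and 13 with the replicate number as a block, and 95 and 84 without Other B-ALL. In 2 versions chosen after the data were seen, 57 were higher and 7 lower with BCR-ABL1 alone, sharing 23 of the 71 calls, and 44 and 31 with BCR-ABL1-like alone, sharing 30. Single libraries moved the balance of directions too, to 39 and 34 without KMT2Ar replicate 1, 39 and 13 without BCR-ABL1-like replicate 1, and 72 and 20 without BCR-ABL1-like replicate 3. The list of BCR-ABL1 and BCR-ABL1-like associated genes, fixed beforehand, had 3 of 18 genes higher, JCHAIN, CA6 and PON2, and 9 when adjusted over the list alone (camera adjusted p = 2.89e-20, or 0.00111 with an estimated correlation). Of 12 ETV6-RUNX1 associated genes, DSC3 and KCNN1 among them, 5 were lower (camera adjusted p = 4.47e-16, or 0.000832 with an estimated correlation). This too reflects ETV6-RUNX1 on the other side, at a mean log2 level of 5.86: BCR-ABL1 at 1.58 and BCR-ABL1-like at 1.88 were not below KMT2Ar at 1.57 or Other B-ALL at 1.42.

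BCR-ABL1 was then compared with BCR-ABL1-like directly. SKAP2, an adaptor of cell adhesion signalling, averaged 3.35 ± 5.68 TPM in BCR-ABL1 and 95.2 ± 43.1 TPM in BCR-ABL1-like (SD, n = 3 each; log2 difference -5.27 ± 1.03 (SE), limma adjusted p = 0.0327). FGFBP2 averaged 0.662 TPM in BCR-ABL1 and 38.5 TPM in BCR-ABL1-like (log2 difference -4.71 ± 0.80 (SE), adjusted p = 0.00905), and the interleukin receptor gene IL7R 1.37 and 72.0 TPM (adjusted p = 0.0348). RTL8B averaged 13.8 ± 6.65 TPM in BCR-ABL1 and was listed at 0 in the 3 BCR-ABL1-like libraries (adjusted p = 0.00239), as was CCN3, at 135.6 ± 199 TPM in BCR-ABL1. The libraries did not overlap in any of these 5 genes, which the naming rule required of those named as largest changes. Only the RTL8B call held under every alternative: over 12 alternatives the adjusted p ran from 0.023 to 0.212 for IL7R and from 0.00609 to 0.122 for SKAP2. Both were lost without BCR-ABL1 replicate 1, BCR-ABL1 replicate 2 or BCR-ABL1-like replicate 1, IL7R also without BCR-ABL1-like replicate 2 (adjusted p = 0.212), SKAP2 also without BCR-ABL1-like replicate 3 (adjusted p = 0.0859), and FGFBP2 without BCR-ABL1 replicate 2 (adjusted p = 0.0531). IL7R and SKAP2 were also lost with no filter, under quantile normalization, over genes with a mean of at least 10 TPM and with the replicate number as a block. FGFBP2 was also lost with a pseudocount of 0.1 TPM (from 0.00554 to 0.0851 over 11 alternatives), and CCN3 over genes with a mean of at least 10 TPM (from 0.000325 to 0.0961 over 12). In total 20 genes were higher and 6 lower in BCR-ABL1, and 49 and 7 without BCR-ABL1 replicate 3. The balance of directions rested on single libraries: 20 were higher and 17 lower without BCR-ABL1-like replicate 1, 15 and 16 without BCR-ABL1-like replicate 2, 16 and 19 without BCR-ABL1-like replicate 3, and 20 and 2 without BCR-ABL1 replicate 2. T and NK markers lay in the same direction as FGFBP2 and IL7R, at a mean log2 level of 2.26 ± 0.83 in BCR-ABL1 and 3.52 ± 0.49 in BCR-ABL1-like (SD, n = 3 each; exact permutation p = 0.2, adjusted p = 0.581). That test cannot reach 0.05 with 3 against 3 libraries. Of 21 leukaemia and lymphoid driver genes 1 was lower, IL7R, and 7 when adjusted over the list alone (camera adjusted p = 9.15e-06, or 0.101 with an estimated correlation).

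The iAMP21 libraries were compared with the 5 subtypes to ask what the amplification goes with. STAB1, a scavenger receptor gene, averaged 193.1 ± 67 TPM (SD, n = 2) in iAMP21 and 12.95 TPM or less in the subtype means (log2 difference 5.67 ± 0.71 (SE), limma adjusted p = 0.00015). GADD45A, a growth arrest gene, was lower, at 8.46 ± 0.291 TPM against 28.1 to 354.5 (log2 difference -3.60 ± 0.49 (SE), adjusted p = 0.000341). On chromosome 21, TTC3 averaged 552.5 ± 95.6 TPM against at most 93.9 and HMGN1 1008 ± 77.1 TPM against at most 315.5. Their calls were lost without iAMP21 replicate 1 (adjusted p = 0.405 and 0.338) and without iAMP21 replicate 2 (adjusted p = 0.14 and 0.146), and with the replicate number as a block, with adjusted p from 0.00208 to 0.405 for TTC3 and from 0.00148 to 0.338 for HMGN1 over 31 alternatives. In each of these genes both iAMP21 libraries lay beyond the 22 others, and the calls for STAB1, NSG1 and GADD45A held under every alternative tried. In total 80 genes were higher and 4 lower, and 30 were called without iAMP21 replicate 1. Of the 18 chromosome 21 genes of the commonly amplified region 2 were higher, and 8 when adjusted over the list alone (camera adjusted p = 5.85e-11, or 0.0598 with an estimated correlation). The median over 243 expressed genes of chromosome 21 was 0.27 and 0.37 in the iAMP21 libraries on the log2 scale against -0.10 ± 0.24 (SD, n = 22) in the others, a difference of 0.42 (exact permutation p = 0.0507, 2-sided). Of the 22 others, 2 lay above the lower iAMP21 library. JCHAIN at 3368 ± 933 TPM, CA6 at 33.6 ± 13 TPM and PON2 at 38.9 ± 11.6 TPM (SD, n = 2) were near the BCR-ABL1 and BCR-ABL1-like means without being called. Of the 18 genes associated with those subtypes 0 were called in limma and 7 were higher when adjusted over the list alone (camera adjusted p = 0.000273, or 0.219 with an estimated correlation).

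The knockout asks what ERG does in leukaemia cells. In REH, ERG stood at 109.7, 92.8 and 155.3 TPM with ERG guides 1, 4 and 6, and at 245.9 and 235.8 TPM with control guides 1 and 2. In SEM it stood at 46.2, 25.6 and 29.7 TPM with those ERG guides and at 53.03 and 46.1 TPM with the control guides. The log2 difference was -1.04 ± 0.21 (SE; limma adjusted p = 0.0851) in REH and -0.58 ± 0.26 (SE; adjusted p = 0.762) in SEM. In REH the adjusted p ran from 0.0255 to 0.325 over 10 alternatives, and ERG was called only over genes with a mean of at least 10 TPM, a filter chosen after seeing the data. ERG RNA remained in every library with an ERG guide, and RNA level does not show how much protein was made. In SEM, the library with ERG guide 1 was above the lower control library.

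In REH, SOWAHD fell from 64.1 ± 9.08 TPM (SD, n = 2) to 8.66 ± 0.981 TPM (SD, n = 3), a log2 difference of -2.75 ± 0.22 (SE; limma adjusted p = 0.0149). CDK2AP1, a regulator of cyclin-dependent kinase, rose from 43.4 to 294.2 ± 118 TPM (log2 difference 2.65 ± 0.34 (SE), adjusted p = 0.0409), CYBB from 62.7 to 184.4 TPM, and the metallothionein gene MT2A from 56.8 to 169.5 TPM. Among genes of antigen presentation HLA-DPB1 fell from 144.2 to 53.3 TPM (log2 difference -1.43 ± 0.17 (SE), adjusted p = 0.0357), with HLA-DOA by 1.02. The tetraspanin gene CD9 fell by 1.52 on the log2 scale (adjusted p = 0.0291). In these genes the 3 libraries with ERG guides lay on 1 side of both control libraries, as the naming rule required of the largest changes. In total 11 genes were higher and 19 lower of 18391, and 2709 had an unadjusted p under 0.05. None of the 16 named calls held under every alternative: with no filter 0 genes were called in limma, and over 10 alternatives the adjusted p ran from 0.00186 to 0.181 for SOWAHD and from 0.00472 to 0.28 for HLA-DPB1. SOWAHD was lost without ERG guide 1 (adjusted p = 0.103), ERG guide 4 (adjusted p = 0.156) or control guide 2 (adjusted p = 0.0549), and HLA-DPB1 without ERG guide 1, 4 or 6 or control guide 2 (adjusted p from 0.104 to 0.164) and with a pseudocount of 0.1 TPM. The count was 0 without ERG guide 1, 0 without ERG guide 4, 10 without ERG guide 6, 277 without control guide 1 and 1 without control guide 2.

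MHC class II genes fell as a list in REH: 2 of 11 were called, 10 when adjusted over the list alone, and the median log2 difference was -1.14 (camera adjusted p = 3.89e-19, or 0.573 with an estimated correlation). Their mean log2 level was 6.66 ± 0.01 (SD, n = 2) with control guides and 5.83 ± 0.21 (SD, n = 3) with ERG guides. Of 17 p53 target genes 0 were called in limma, and 6 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.000129, or 0.573 with an estimated correlation). CDKN1A, the largest p53 riser, had a log2 difference of 1.28 ± 0.25 (SE; adjusted p = 0.0821). An exact permutation test of 3 against 2 libraries cannot reach 0.05, so these lists rest on the limma model.

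In SEM 0 genes were higher and 1 was lower of 17481, and 1170 had an unadjusted p under 0.05 in limma. The lower gene was the small RNA pseudogene RN7SL4P (log2 difference -4.92 ± 0.33 (SE), adjusted p = 0.00179), named after its values were seen. The count was 20 without ERG guide 1 and 2 without control guide 1. MHC class II genes had a median log2 difference of -0.50, with 0 of 11 called in limma also when adjusted over the list alone (camera adjusted p = 1.95e-09, or 0.952 with an estimated correlation). Tested directly, the effect on the list in SEM minus that in REH had a median of 0.61 (camera adjusted p = 0.0241, or 0.886 with an estimated correlation). Of 21551 genes tested for a difference between the lines, 4 were higher and 1 lower: FGFBP2 (log2 2.89 ± 0.34 (SE), limma adjusted p = 0.0307), SOWAHD (2.72 ± 0.31 (SE), adjusted p = 0.0273) and, named after their values were seen, AC091559.1, AC125603.1 and RN7SL4P. Within single lines AC091559.1 was tested only in REH, at a log2 difference of -2.88, and RN7SL4P only in SEM. The differences between the lines in these 2 genes therefore come mainly from 1 line. FGFBP2 fell by 2.23 in REH and changed by 0.65 in SEM, and SOWAHD by -2.75 and -0.03. Over 16 alternatives their adjusted p ran from 0.00279 to 0.246, and both were lost without REH ERG guide 1 or 4, REH control guide 2, SEM ERG guide 4 or 6, or either SEM control guide, with a pseudocount of 0.1 TPM and with the replicate block. FGFBP2 was also lost under quantile normalization and without SEM ERG guide 1. The count of 5 became 0 without REH control guide 2, without SEM ERG guide 6 or without SEM control guide 2, 1 without REH ERG guide 4, SEM ERG guide 4 or SEM control guide 1, 2 without REH ERG guide 1 and 9 without REH control guide 1. Of the 21 genes called in REH and tested in SEM, 13 (61.9%) had the same sign in SEM. No gene called in SEM was among the 14808 tested in both lines, so shared calls were not possible, and across these genes the Spearman correlation of the effects was -0.0453. Genes are not independent replicates.

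**Figure D4:**
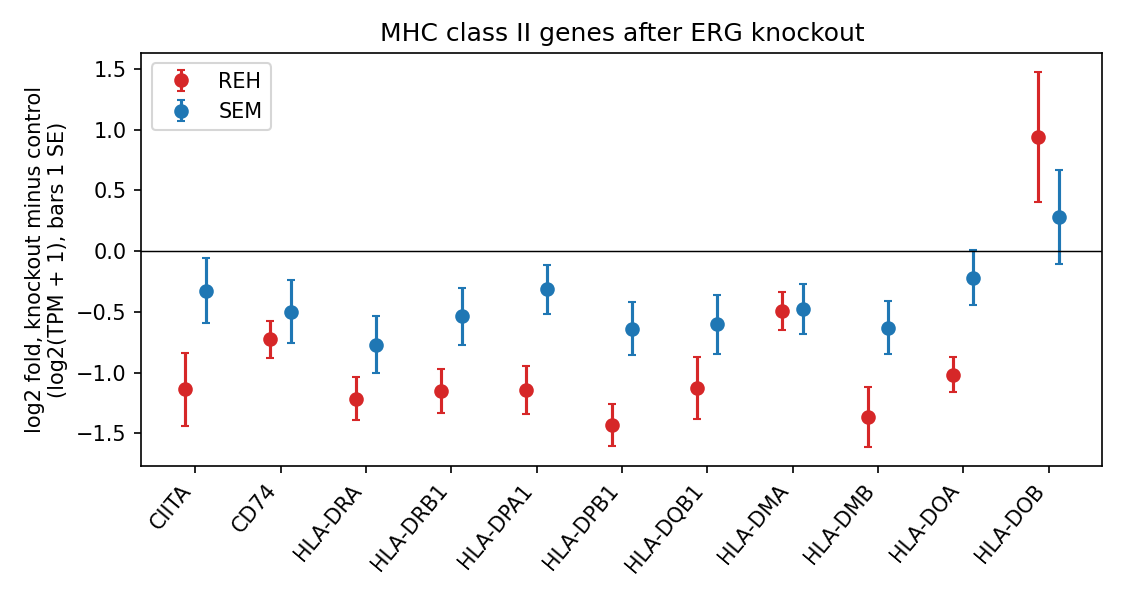
Log2 difference between ERG guides and control guides for the MHC class II genes in REH and in SEM, with bars of 1 SE. HLA-DRA lies at -1.22 in REH and -0.77 in SEM, and HLA-DOB is above 0 in both lines.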

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

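The tests on the direct comparison of BCR-ABL1 with BCR-ABL1-like and on KMT2Ar replicate 1 were chosen only after the result was seen. The tests on proliferation genes and the splits of the samples were written before.

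Single libraries lay far from the rest of their group in 12 of 117 group values tested, where chance gives about 5.8 at 1 in 20. In KMT2Ar replicate 3 the mean log2 level of myeloid markers was 5.10 and that of plasmacytoid dendritic markers 5.07, and the log2(TPM + 1) of ALOX5 was 4.18 and of SERPINB9 4.27. The same library listed 17119 genes above 0, the fewest of all. In KMT2Ar replicate 5 ERG stood at 10.6 TPM and the log2(TPM + 1) of MME at 1.62. In KMT2Ar replicate 1 HOXA10 was listed at 0. Among the other groups, the log2(TPM + 1) of CLIC5 was 2.98 in ETV6-RUNX1 replicate 5, that of S100A11 2.49 in ETV6-RUNX1 replicate 6, that of LILRA4 1.57 in Pro-B replicate 3 and that of EGFL7 4.47 in Pre-B replicate 3. The mean log2 level of megakaryocyte markers was 0.80 in CLP replicate 1. No explanation was tested for these values apart from those for KMT2Ar replicate 1.

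The effect of the ERG guides differed between the lines by the limma interaction test in FGFBP2, by a log2 of 2.89 (SEM minus REH; adjusted p = 0.0307), and in SOWAHD, by 2.72 (adjusted p = 0.0273). Both fell in all 3 REH libraries with ERG guides. Neither call held under every alternative, with adjusted p from 0.00279 to 0.246 over 16 alternatives, and no explanation was tested.

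KMT2Ar replicate 1 listed HOXA9, HOXA7 and HOXA10 at 0, against 76.6 to 613 TPM of HOXA9 and 30.9 to 122 TPM of HOXA10 in the other 4 KMT2Ar libraries. It nevertheless held 463 TPM of LAMP5, 93.7 TPM of CSPG4, 21.3 TPM of MEIS1 and 0.255 TPM of MME. Low depth is argued against, since 3 of the other 4 KMT2Ar libraries, all with HOXA9 above 10 TPM, listed fewer genes above 0 than its 26380. A mislabelled sample from another subtype of this series was also considered. Outside the HOXA cluster, 296 genes separated the other KMT2Ar libraries from 17 libraries of the other subtypes with at least 3 libraries. In replicate 1, 142 of them, or 48%, lay on the KMT2Ar side, between the bounds set for that test and so undecided. A second test, added after that undecided outcome, scored each of those 17 libraries against the rest. They reached at most 24.9%, which argues against a mislabelling from their subtypes. Each of the other KMT2Ar libraries, scored on genes separating its own 4 fellows, replicate 1 among them, gave 68.8% to 84.2%. These gene sets differ from that used for replicate 1. The iAMP21 and hyperdiploid libraries were not scored, so a mislabelling from those groups stays open. A KMT2A rearrangement without HOXA expression may account for the library, but the design does not test it, and a sample from outside the series or a mixed sample stays open.

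Between BCR-ABL1 and BCR-ABL1-like, the number of genes above 0 differed without overlap, from 26034 to 28498 in BCR-ABL1 and from 17728 to 18262 in BCR-ABL1-like. Of the 20 genes called higher in BCR-ABL1, 16 were listed at 0 in all 3 BCR-ABL1-like libraries. Their median BCR-ABL1 mean was 10.5 TPM, and 11 of the 20 had a mean of at least 10 TPM. Since these genes were chosen for their difference, that does not decide whether fewer low genes were detected in BCR-ABL1-like. The 6 genes called lower in BCR-ABL1 had a median BCR-ABL1-like mean of 55.2 TPM. They lay higher in BCR-ABL1-like with no overlap, by log2 differences of 3.33 to 5.27. Lower detection in BCR-ABL1-like would not raise a gene there, so the direction of these calls argues against it for them. These genes too were chosen for their difference, so their direction and lack of overlap are no separate test. Scaling fewer genes to the same total would raise the rest alike, and over the genes with a mean of at least 10 TPM the median log2 difference was -0.21 (BCR-ABL1 minus BCR-ABL1-like). The lower calls numbered 17, 16 and 19 without BCR-ABL1-like replicates 1, 2 and 3, and 0 over genes with a mean of at least 10 TPM. Lower detection stays open for the higher genes alone, and chance and a difference between the subtypes for both parts. Library preparation cannot be examined, since the labels give no batch. T and NK markers were higher in BCR-ABL1-like, at a mean log2 level of 3.52 ± 0.49 against 2.26 ± 0.83 (SD, n = 3 each). That difference missed the threshold (exact permutation p = 0.2), and T and NK cells were not tested as a cause.

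Proliferation genes were lower in leukaemia than in Pro-B and Pre-B. Of the 26 genes, 24 were still called lower after quantile normalization, so these calls did not rest on differently shaped distributions of values. That step also gives every library the same total, so it cannot decide whether scaling each library to 1 total is a cause. If the cause were that Pro-B and Pre-B are cycling stages, leukaemia was predicted to lie at or above Immature-B, and it did. The mean log2 level of the list was 5.40 ± 1.09 (SD, n = 22) in leukaemia, above that in Immature-B by 1.19. This difference missed the threshold in a permutation test (exact p = 0.0826). Leukaemia also lay below CLP, at 6.73 ± 0.98 (SD, n = 4). Immature-B had the lowest level of the healthy stages, so lying above it does not decide for this cause. Sorting, handling of the patient samples and the leukaemia itself stay open and were not tested.

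Other splits of the samples were counted for comparisons with at least 3 libraries on each side. For the healthy steps only the real 1 of 35 splits gave as many calls: 206 against at most 7 for Pro-B and CLP, 322 against at most 3 for Pre-B and Pro-B, and 714 against at most 29 for Immature-B and Pre-B. Among the 8 splits that part as many same-number pairs, the highest others were 0, 0 and 29, and the splits that part fewer reached 7, 3 and 6. As same-number healthy libraries deviate together, those 8 are the comparable ones, and they are too few for a share under 0.05. In the leukaemia comparison the real split gave 2434 calls and the highest other of 100 gave 363, but these splits do not follow the pairing of Pro-B and Pre-B libraries, and with the number as a block the count was 1267. Only the real split of 100 gave as many calls for ETV6-RUNX1 (1112 against 12), KMT2Ar (1509 against 23) and both BCR-ABL1 groups (71 against 13). These splits mixed the labels of all 5 subtypes, so differences between them widened the spread and could hold the counts down. The result argues against chance labels over all 5 subtypes, but does not exclude chance for a single comparison. For BCR-ABL1 against BCR-ABL1-like, the real split gave 26 calls and the highest other 14, and 10 splits are too few for a share under 0.05.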

How the results depend on the processing

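The alternatives with mean TPM of at least 10, without the healthy libraries numbered 2, without BCR-ABL1-like, with BCR-ABL1 or BCR-ABL1-like alone, and the centred chromosome 21 version were chosen only after the data were seen. Of 8331 values recomputed for 400 named genes and lists, 7244 kept their side of the threshold, 1074 fell below it, 11 passed it and 2 reversed. A change of direction was counted as reversed only where the value was called in at least 1 of the 2 fits. Uncalled values that changed direction are therefore among the 7244. Left-out libraries gave 642 of those that fell below the threshold. SPIB in leukaemia turned to 0.231 against Pro-B alone and CHAF1B to 0.069 against all 4 healthy stages. Where a count or call changed, the cause was not tested.

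With the replicate block the counts were 856, 922 and 3076 for the healthy steps (Pro-B, Pre-B and Immature-B), 1267 for leukaemia, 704 for ETV6-RUNX1, 1178 for KMT2Ar, 29 for both BCR-ABL1 groups, 18 for BCR-ABL1 against BCR-ABL1-like, 36 for iAMP21 and 0 for the difference between the lines (limma; 2420 at an unadjusted p under 0.05 without the block). The block for leukaemia was the random one, so its count comes from another model than the rest. All 1267 leukaemia calls were among the 2434 without the block. Subtype libraries share only a number: 7 of 34 same-number pairs correlated over 0.1, and ERG guides across lines at -0.081 to -0.060 in 3 pairs. ERG was called for ETV6-RUNX1 with the block (log2 2.15, limma adjusted p = 0.0326; 0.0275 to 0.164 over 29 alternatives). Under the block no healthy list call was lost, and 14, 11 and 12 lists were called for the healthy steps against 13, 9 and 8 without it. No paired analysis was possible because ERG and control guides within REH and within SEM share only number 1.

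With a pseudocount of 0.1 TPM the counts were 113 for Pro-B, 50 for BCR-ABL1 against BCR-ABL1-like, 23 for iAMP21, 12 for REH and 0 for the difference between the lines. With no filter they were 98 for Pro-B, 733 for ETV6-RUNX1, 965 for KMT2Ar, 47 for BCR-ABL1 against BCR-ABL1-like, 204 for iAMP21, 0 for REH, 0 for SEM and 30 for the difference. With array quality weights they were 322 for Pro-B, 1560 for Immature-B, 4011 for leukaemia, 2427 for KMT2Ar, 291 for iAMP21, 13 for REH and 4 for SEM. With mean TPM of at least 10 they were 71 for Pro-B, 539 for ETV6-RUNX1, 28 for both BCR-ABL1 groups, 2 for BCR-ABL1 against BCR-ABL1-like, 10 for iAMP21, 275 for REH, 5 for SEM and 14 for the difference. Quantile normalization gave 140 for REH and 2 for the difference, made 59.9% of ETV6-RUNX1 calls higher against 70.3%, and 50% against 80% for the difference, and moved the median of all genes from 0.148 to -0.011 there and from 0.115 to -0.011 in SEM. With fewer or other groups, Pro-B gave 19 (its 2 groups only), Immature-B 1489 (without number 2), leukaemia 729 against Pro-B and 1413 against Pre-B, KMT2Ar 984 and both BCR-ABL1 groups 179 (without Other B-ALL). Immature-B had 142 genes higher and 398 lower with a pseudocount of 0.1 TPM and 147 and 410 with mean TPM of at least 10, against 324 and 390. With an estimated correlation 20 of 88 list calls held. Chromosome 21 in iAMP21 differed by 0.46 in the centred version (exact permutation p = 0.0362) and by 0.28 at mean TPM of at least 10 (exact permutation p = 0.348), where 9 of the 22 others lay above the lower iAMP21 library.

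Leaving out each library gave 75 to 289 genes for Pro-B, 203 to 297 for Pre-B, 328 to 643 for Immature-B, 1766 to 2628 for leukaemia, 868 to 1214 for ETV6-RUNX1, 731 to 1707 for KMT2Ar, 49 to 98 for both BCR-ABL1 groups, 22 to 56 for BCR-ABL1 against BCR-ABL1-like, 30 to 100 for iAMP21, 0 to 277 for REH, 1 to 20 for SEM and 0 to 9 for the difference. A side left with 1 library was assumed to vary like the others. Depth is unknown, so what it limits cannot be given.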

Other observations

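The test of ERG against MHC class II was written before its result was seen, and no test here was chosen after.

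Pseudoautosomal genes were close to absent from the tables: of 18 protein-coding ones, 17 had a highest value under 0.1 TPM over all 50 libraries and 9 were listed at 0 in each, among them CRLF2, while CD99 reached 7.41 TPM. CRLF2, a gene of the BCR-ABL1-like list, therefore could not be read from these values.

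Ribosomal protein genes made up 16.1 ± 2.86% of TPM in Other B-ALL (SD, n = 4), 10.7 ± 2.21% in BCR-ABL1 (SD, n = 3) and 5.73 ± 2.72% in ETV6-RUNX1 (SD, n = 7). The hyperdiploid library held 135.8 TPM of ERG, and its chromosome 21 median was 0.18 on the log2 scale, 0.62 in the centred version and 0.80 at mean TPM of at least 10, with 4, 1 and 1 of the 22 others above it.

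MHC class II genes were lower with ERG guides in REH and higher in ETV6-RUNX1 leukaemia, although both camera calls were lost with an estimated correlation (adjusted p = 0.573 and 0.386). A hypothesis is that ERG may raise these genes in that subtype. Their level did not follow ERG in every group. It was 9.03 ± 0.70 (SD, n = 3) in BCR-ABL1 and 9.11 ± 0.80 (SD, n = 7) in ETV6-RUNX1, at ERG means of 101.8 and 195.2 TPM. From Pre-B to Immature-B it rose from 7.98 to 9.77, while ERG fell from 4.70 to 0.187 TPM. SEM, a KMT2A-rearranged line, went in the same direction as ERG: the level was 4.97 with ERG guides and 5.375 with control guides. The ERG means there were 33.8 and 49.6 TPM, and neither ERG nor an MHC class II gene was called. Over the 7 ETV6-RUNX1 libraries, Pearson's r between the ERG level and the mean MHC class II level was 0.176 (exact permutation p = 0.684) and Spearman's rho was 0.357 (exact permutation p = 0.444), with an adjusted p of 0.684 for both of 2 tests. Without the 2 libraries farthest from the median of ERG, r was 0.671. No relation was detected, and 7 libraries are too few to exclude one.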
